A study of Mus musculus with 5 samples.

How the data were processed

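Chromatin immunoprecipitation followed by Solexa sequencing was carried out on secondary mouse embryonic fibroblasts that carry doxycycline-inducible Klf4, Sox2 and Oct4. Per the labels' protocols, inducible pluripotent cells were injected into blastocysts, fibroblasts were taken from the chimeric embryos at 13.5 days post coitum, and the descendants of the injected cells were selected with puromycin at 2 µg/ml for 48 hours in medium with 10% serum. Sonicated chromatin had a mean fragment size of 500 bp, 18 cycles of amplification were used, and gel slices from 150 to 350 bp were taken, which corresponds to inserts of 50 to 200 nt. The 5 libraries were 1 for the transcription factor E2F4, 1 for RNA polymerase II (RNA Pol II, antibody 8WG16), 1 for histone H3 trimethylated at lysine 27 (H3K27me3) and 2 of whole cell extract without antibody (WCE).

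The deposited values are positions of aligned reads, signed by strand, and per the file headers they were placed on mouse build mm8 with bowtie (settings -e 70, -k 2, -m 2, -n 2, with -l 26 for E2F4, RNA Pol II and WCE replicate 1 and -l 36 for H3K27me3 and WCE replicate 2). The submitters' processing notes name Bowtie, and its version is not given in the sources used here. Each deposited list has a section of reads with 1 placement and a section with an even number of lines in every library, read here as reads listed at 2 places. Read lengths of 26 and 36 bp were taken from the alignment settings. The first section held 2489430 reads for E2F4, 3545176 for RNA Pol II, 10778012 for H3K27me3, 525513 for WCE replicate 1 and 12301138 for WCE replicate 2. A count of 0 allows a share of up to 0.00012% of the E2F4 reads and 0.000571% of the reads of WCE replicate 1 (3 counts of the total).

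From these lists, reads of the first section were kept once per position and strand, and 5′ ends were moved 60 bp towards the 3′ side. Reads were counted in bins of 500 bp for E2F4 and RNA Pol II and of 2000 bp for H3K27me3 on chromosomes 1 to 19, X and Y. Each bin was compared with the summed WCE libraries by a one-sided exact conditional binomial test, with libraries scaled by their totals on the autosomes. Benjamini-Hochberg adjustment ran over bins with at least 1 antibody read. Bins with an adjusted p under 0.01 and a ratio of at least 3 (pseudocount 1 read) were called, and called bins with no more than 1 bin between them were joined. Intervals are exact (Clopper-Pearson) at 95%, and those on read counts cover counting error only. With 1 library per antibody there is no replicate spread, so every test compares libraries, not conditions. Amplified reads without molecular identifiers are not independent molecules.

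Overlap means at least 1 shared bp. It was set against 1000 circular shifts of the first set along each chromosome, against independent lists over 2 kb bins, the latter also within 5 classes of WCE read count, and against 100 simulated draws of unchanged libraries that share the WCE libraries, in which as many 2 kb bins with the lowest p were taken as the observed regions touch. These draws used WCE rates averaged over 10 kb, so narrower WCE peaks are absent from them. The alternatives below and the distances to H3K27me3 regions used 100 shifts. Regions of a genome are not independent replicates, so overlaps carry no p-value. Intervals on shares of regions treat each region as an independent trial, and they do not cover the change of a share with the settings. Flanks are the sequence 5 to 20 kb from a region. Summits are the densest 200 bp of a region. Densities are reads per kb per 10000000 distinct autosomal reads. Named regions are the 5 longest of H3K27me3 and the 5 of E2F4 and of RNA Pol II with the highest lower limit of the ratio to WCE; others are said to have been chosen after their values were seen.

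The tests for regions, the naming rule and most alternatives were fixed before the data were examined. The overlap of regions, the shifts, the flank comparisons and the comparison with gene density were chosen after the files were seen, because the only gene table used here is of assembly GRCm38.p6 and the reads are on mm8. The table served only to count protein-coding genes per chromosome. Planned counts of promoters, promoter overlaps, the 23 gene lists, the RNA Pol II ratio of promoter to gene body and the exon signature of the transgenes were therefore not run, and no gene is named.

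The caller was tested on simulated data with 200 bins raised by known folds over the WCE level. It called 12% of bins raised 16-fold and 50% of those raised 32-fold at the E2F4 depth, 32% and 66% at the RNA Pol II depth, and 92% and 98% at the H3K27me3 depth. In unchanged bins it called 0, 0 and 1. These bins were drawn from the same smoothed rate for antibody and WCE, as the test assumes, so few calls were built in. The rate of false calls in the real libraries was not measured. Between the real WCE libraries, 4776 regions were called in replicate 1 over replicate 2 and 1 the other way. Alternatives left out each WCE library, kept all reads, scaled on background bins, used an adjusted p under 0.0001, a fold minimum of 5, no shift, thinned libraries, bins of 1000 bp, both sections, a uniform background, H3K27me3 regions of at least 10 kb, and a different WCE library for each antibody of a pair. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.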

Results

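The series mapped where E2F4, RNA Pol II and H3K27me3 lie in the genome of secondary mouse embryonic fibroblasts. E2F4 is a member of the E2F family of cell cycle transcription factors, antibody 8WG16 recognises the C-terminal repeats of the largest RNA Pol II subunit, and H3K27me3 is the histone mark laid down by Polycomb group methyltransferases. Each antibody had 1 library, and 2 libraries of WCE served as background. After repeats of a position were removed, the libraries held 2016814 reads for E2F4, 3177248 for RNA Pol II, 9623860 for H3K27me3, 445794 for WCE replicate 1 and 11428107 for WCE replicate 2. The removed repeats had made up 18.98%, 10.4%, 10.7%, 15.2% and 7.10% of the reads of the first section. The distance between strands peaked at 178 bp for E2F4, 142 bp for RNA Pol II, 145 bp for H3K27me3 and 153 bp for WCE replicate 2. WCE replicate 1 had instead a sharp peak at 43 bp, 37.0 times its level at 380 to 399 bp, and it supplied 417799 of the 11644392 autosomal background reads.

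The first question was where each antibody was enriched over WCE. E2F4 was enriched in 6502 short regions that covered 4.39 Mb, 0.171% of the mapped genome, with a median length of 500 bp and a longest of 3000 bp. They held 17.4% of the E2F4 reads (95% interval 17.4 to 17.5) against 1.36% of the WCE reads, a ratio of 12.8 (12.7 to 12.9). The median region had a ratio of 8.86 (quartiles 6.17 and 15.2). The test called bins at an adjusted p under 0.01, and no region count has a replicate check. Against WCE replicate 1 alone, the shallow library, only 1149 regions were called.

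The E2F4 region with the highest lower limit lay on chromosome 5 from 114534501 to 114535000 (mm8, as all positions here) and held 88 E2F4 reads against 1 WCE read, a ratio of 520 (90.9 to 20756). It held 0 RNA Pol II reads, with an interval of the ratio from 0 to 146, and lay in an H3K27me3 region. Its 64 H3K27me3 reads gave a ratio of 78.6 (13.6 to 3152), so both ratios to the 1 WCE read are imprecise. The next 4 all overlapped RNA Pol II regions. Chromosome 16 from 18162001 to 18162500 had a ratio of 213 (81.3 to 791), chromosome 4 from 88766001 to 88766500 had 156 (78.0 to 367), chromosome 14 from 78185501 to 78186500 had 128 (72.0 to 251) and chromosome 3 from 159430501 to 159431000 had 128 (70.1 to 259). Against WCE replicate 1 alone these 5 regions had 0 background reads, and the lower limits of their ratios were 4.95 to 14.8.

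RNA Pol II was enriched in 13394 regions that covered 16.04 Mb, with a median length of 1000 bp. They held 57.4% of its reads (57.3 to 57.4) against 3.97% of the WCE reads, a ratio of 14.5 (14.4 to 14.5). Of these regions, 139 were at least 5 kb long. The 5 regions with the highest lower limit included 3 close together on chromosome 11, where 87242501 to 87244000 had a ratio of 113 (65.4 to 214), 87238501 to 87240000 had 99.6 (64.5 to 162) and 87259001 to 87260000 had 96.9 (51.9 to 205). The others were chromosome 2 from 60010501 to 60011000, at 226 (61.3 to 1891), and chromosome X from 49293501 to 49302000, at 65.1 (51.0 to 84.4). The longest region, chosen after its values were seen, ran for 28 kb on chromosome 19 from 5822501 to 5850500 at a ratio of 21.3 (19.6 to 23.2). Scaling on background bins raised every RNA Pol II ratio by 1.90 on the log2 scale and the count to 22806, and against WCE replicate 1 alone 6508 regions were called. There the region on X had a ratio of 39.7, and the other 4 with the highest lower limits had 0 background reads and lower limits of 4.34 to 20.3.

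H3K27me3 formed broader regions, 8970 in number and 52.8 Mb in all. Their median length was 2000 bp, 1414 were at least 10 kb and 64 at least 50 kb long. They held 16.5% of the H3K27me3 reads (16.5 to 16.5) against 3.17% of the WCE reads, a ratio of 5.20 (5.18 to 5.21). The 5 longest ran for 116 to 144 kb. On chromosome 19, 44764001 to 44908000 had a ratio of 7.57 (7.06 to 8.12) and 45254001 to 45374000 had 7.44 (6.93 to 8.00). Chromosome 7 from 79368001 to 79492000 had 8.11 (7.57 to 8.70), chromosome 5 from 139748001 to 139868000 had 7.26 (6.78 to 7.78) and chromosome 4 from 136132001 to 136248000 had 5.31 (4.95 to 5.70). None of the 5 overlapped an RNA Pol II region, and their RNA Pol II ratios lay between 0.181 and 0.225 by totals. On background bins these were 0.678 to 0.843, and 3 of the 5 intervals reached 1. Against WCE replicate 1 alone their H3K27me3 ratios were 8.00 to 14.9. The count moved most with the settings: 47 against WCE replicate 1 alone, 16424 with scaling on background bins, which raised every H3K27me3 ratio by 0.49 on the log2 scale, and 4775 when thinned to the E2F4 depth.

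**Figure D1:**
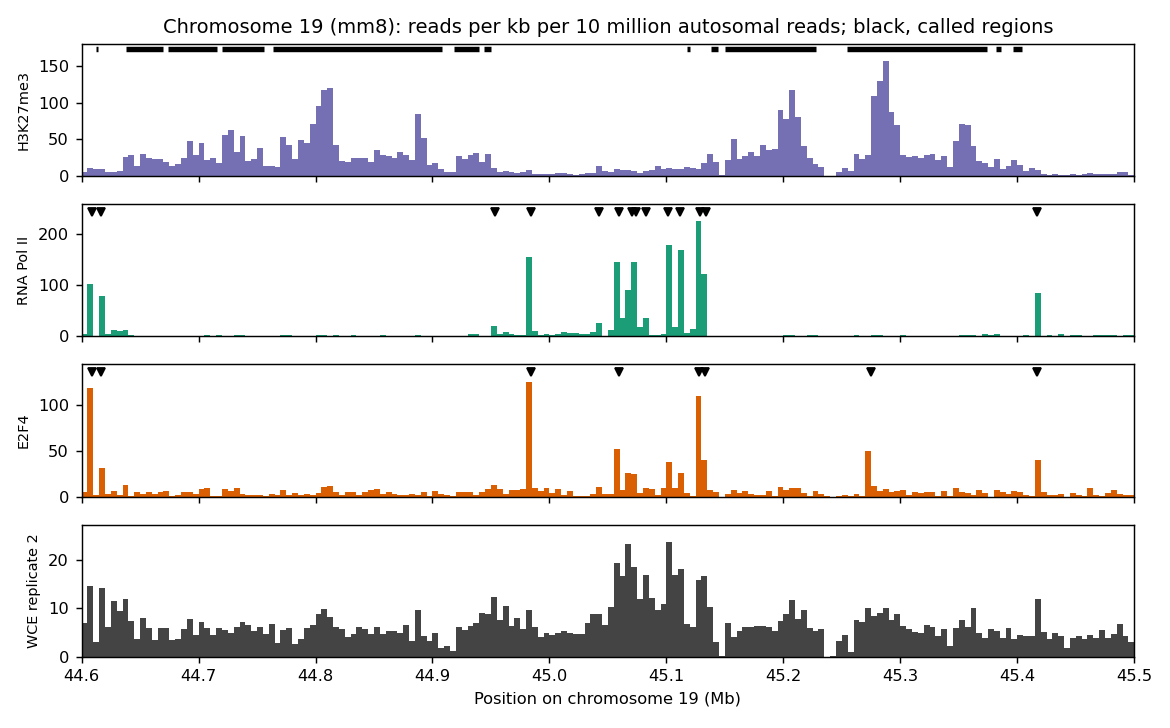
Read density in 5 kb bins (reads per kb per 10000000 autosomal reads) of 4 libraries around the longest H3K27me3 region on chromosome 19 of mm8, with called H3K27me3 regions as black bars and called RNA Pol II and E2F4 regions as triangles at their midpoints. The H3K27me3 regions of 144 and 120 kb hold no RNA Pol II region, and most of the 14 RNA Pol II regions lie between them.

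The second question was whether E2F4 and RNA Pol II occupy the same places. E2F4 regions overlapped RNA Pol II regions in 5689 of 6502 cases, 87.5% (86.7 to 88.3), and 42.02% of the RNA Pol II regions held an E2F4 region. Shifted E2F4 regions overlapped 68.6 times on average (44 to 100 over 1000 shifts), so the observed number was 82.9 times higher. The share depended on the background, at 50.6% (581 of 1149) against WCE replicate 1 alone and 67.7% against a uniform background, added after the data were seen. The share of E2F4 regions with RNA Pol II rose with E2F4 read density, from 46.9% (43.0 to 50.8) in the lowest of 10 equal classes to 97.4% (95.8 to 98.5) in the highest. The share of RNA Pol II regions with E2F4 went from 4.70% (3.63 to 5.98) to 63.8% (61.1 to 66.4) over 10 classes of RNA Pol II density. Longer regions overlap more often by chance, but most of both rises came at a constant median length. Median E2F4 length was 500 bp in classes 1 to 9, where the share reached 95.8%, and 1000 bp only in class 10. Median RNA Pol II length was 500 bp in classes 1 and 2 and 1000 bp from class 3, where the share was 27.1%, to class 10.

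Over 2 kb bins, 6262 were in both sets, 21.0 times the 298 of independent lists and 4.98 times the 1258 expected within classes of WCE read count. Simulated unchanged libraries that share the WCE gave no called region in 100 draws, so as many top bins as in the observed sets were taken instead, and these overlapped 3.49 times as often as independent lists (3.22 to 3.84). Part of the observed excess may come from the shared WCE. The draws hold no narrow WCE peaks, whereas WCE reads were 7.98 times denser in called E2F4 regions than in the genome. In called RNA Pol II regions they were 6.37 times denser. The 3.49 is therefore not a measure of what the shared WCE gives at such regions. With a different WCE library for each antibody the observed number was 92.3 and 149 times that of shifted regions. The shares were then 94.2% and 55.1%.

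The 813 E2F4 regions without an RNA Pol II region had an E2F4 ratio to WCE of 10.1 (9.83 to 10.3) and an RNA Pol II ratio of 1.65 (1.59 to 1.71), which was 6.17 (5.95 to 6.39) with scaling on background bins. Summed over these regions, RNA Pol II reads were 4.07 times as dense as in the flanks (3.94 to 4.19), but the libraries that do not target it were raised there too, WCE replicate 1 by 3.49 times, WCE replicate 2 by 2.80 and H3K27me3 by 2.58. The 7766 RNA Pol II regions without an E2F4 region had an E2F4 ratio of 1.95 (1.93 to 1.96), above WCE although no E2F4 region was called there. WCE replicate 2 was denser at the summits, 4.002 times its level 4 to 5 kb away at E2F4 summits and 3.43 times at RNA Pol II summits. WCE replicate 1 was lower there, at 0.715 and 0.561 times.

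**Figure D2:**
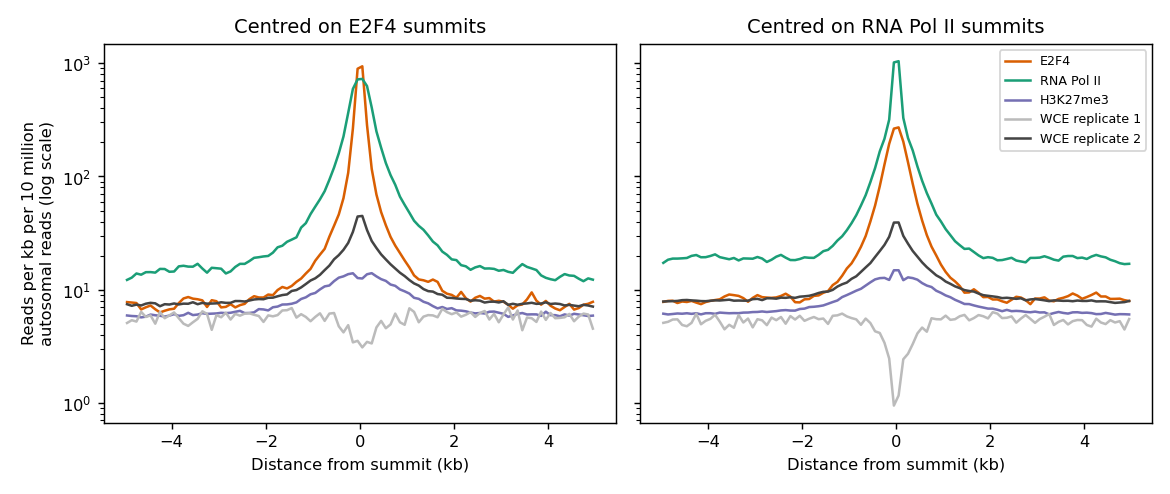
Mean read density (reads per kb per 10000000 autosomal reads, log scale) in 100 bp steps within 5 kb of 6502 E2F4 summits and 13394 RNA Pol II summits, 1 line per library. E2F4 and RNA Pol II peak at both sets of summits, WCE replicate 2 and H3K27me3 rise less, and WCE replicate 1 dips.

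**Figure D3:**
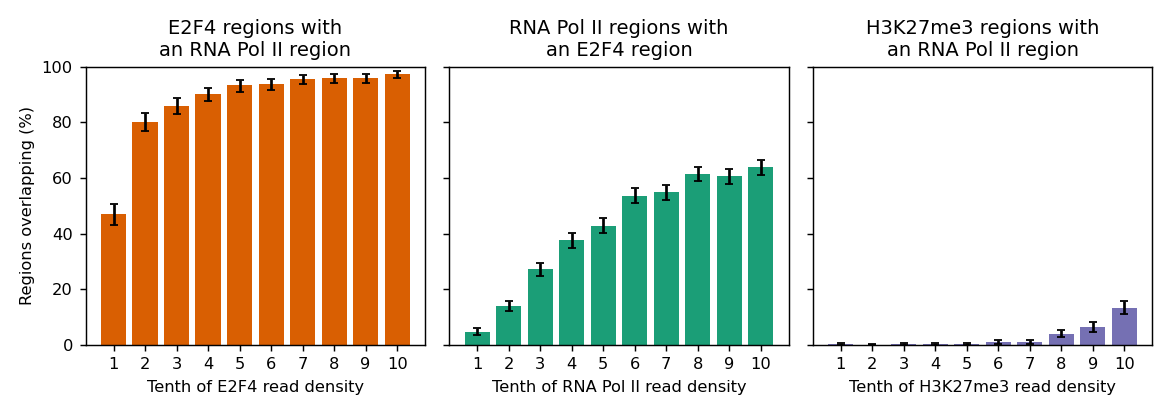
Percentage of regions that overlap a region of the other antibody, by class of read density from lowest (1) to highest (10), each class holding an equal share of the regions, with exact 95% intervals as error bars. E2F4 regions go from 46.9% to 97.4%, RNA Pol II regions from 4.70% to 63.8% and H3K27me3 regions from 0.223% to 13.3%. Median H3K27me3 length goes from 2000 to 6000 bp, but it is 6000 bp throughout classes 8 to 10, where the share goes from 3.90% to 13.3%.

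The third question was how H3K27me3 lies relative to the other proteins. RNA Pol II reads were less dense in H3K27me3 regions than in their flanks, at 0.577 (0.571 to 0.582), whereas WCE replicate 2 stood at 1.05 of its flanks and the shallow WCE replicate 1 at 0.786 (0.766 to 0.806). Against WCE the direction depended on the scaling, with 0.445 (0.441 to 0.450) by totals and 1.67 (1.65 to 1.68) on background bins. The 235 regions that overlapped an RNA Pol II region held 19167 of the 44681 RNA Pol II reads. They stood at 2.90 by totals, 10.8 on background bins and 2.44 of their flanks. The other 8735 stood at 0.272 (0.269 to 0.276) by totals, 1.02 (1.01 to 1.03) on background bins and 0.357 (0.352 to 0.361) of their flanks. This split rests on the RNA Pol II calls themselves. Inside the first 5 kb of H3K27me3 regions of at least 10 kb, RNA Pol II density was 0.413 of that 10 to 20 kb outside, and E2F4 density was 0.949. E2F4 reads in H3K27me3 regions were at 0.825 of WCE (0.818 to 0.833) and at 1.01 of their flanks (0.996 to 1.02), where no difference was detectable.

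Only 235 of 8970 H3K27me3 regions, 2.62% (2.30 to 2.97), overlapped an RNA Pol II region, against 317 on average after shifting (244 to 392), a ratio of 0.741. This shortfall depended on the background, and against a uniform one the ratio was 4.26. An adjusted p under 0.0001 gave 1.01, thinning gave 1.10 and WCE replicate 1 alone, with 47 regions, gave 4.35. Each of these lay within its shifted range, the last with 2 overlapping regions. With H3K27me3 against WCE replicate 2 and RNA Pol II against replicate 1 it was 0.183. The share of H3K27me3 regions with RNA Pol II rose with H3K27me3 read density, to 13.3% (11.1 to 15.7) in the highest of 10 classes. That class held 119 of the 235. Median length was 6000 bp in classes 8 to 10, where the share went from 3.90% to 13.3%. No shifted regions were set against single classes. Over 2 kb bins the overlap was 0.638 times that of independent lists, and 0.547 times that expected within classes of WCE read count. Unchanged libraries sharing the WCE gave 5.67 (5.40 to 6.01). They were drawn from WCE rates averaged over 10 kb, so the 5.67 cannot serve as a bound for the observed regions. Overlap with E2F4, at 131 regions or 1.46% (1.22 to 1.73), lay within the range of shifted regions (110 to 208). Its ratio of 0.857 likewise changed direction, to 4.37 against a uniform background, 1.42 after thinning and 20 against WCE replicate 1 alone, where 2 regions overlapped.

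Seen from the other side, 263 RNA Pol II regions, 1.96%, overlapped H3K27me3 regions. Whether both lay on the same chromosomes of the same cells was not measured. Outside direct overlap, RNA Pol II regions were near H3K27me3 regions more often than shifted ones. There were 528 at 0 to 5 kb, 1.28 times the shifted mean, 1323 at 5 to 20 kb, 1.81 times, and 4444 at 20 to 100 kb, 1.99 times. At 100 kb or more lay 6836, 0.708 times. E2F4 regions gave 1.17, 1.80, 1.99 and 0.707 times in the same distance classes. Their 236 at 0 to 5 kb lay within the shifted range (162 to 260).

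Across chromosomes 1 to 19 and X, regions per Mb followed the density of protein-coding genes (GRCm38.p6). Pearson's r was 0.803 for E2F4, 0.916 for RNA Pol II and 0.730 for H3K27me3, with Spearman's rho of 0.869, 0.940 and 0.838. Permutation tests (two-sided, 100000 permutations) gave p = 1e-05, the smallest they can give, for r and rho of E2F4 and RNA Pol II, and p = 0.0003 for r and 2e-05 for rho of H3K27me3. Adjusted over the 3 antibodies by Benjamini-Hochberg these were 1.5e-05, 1.5e-05 and, for H3K27me3, 0.0003 and 2e-05. Without chromosomes 7 and 11, the farthest from the median, r was 0.841, 0.938 and 0.728. Chromosomes are not independent replicates. Read density of WCE replicate 2 also differed between autosomes, from 0.815 of their mean on chromosome 14 to 1.34 on chromosome 11. The relation to gene density was not separated from read density. Chromosome 11 had 4.85 E2F4, 9.87 RNA Pol II and 5.55 H3K27me3 regions per Mb, and chromosome X 1.03, 2.66 and 0.548. Read density on X was low in 4 of the libraries, at 0.324 of the autosomal mean for E2F4, 0.309 for RNA Pol II, 0.216 for H3K27me3 and 0.252 for WCE replicate 2, which lowers the power to call regions there. WCE replicate 1 had 0.976.

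**Figure D4:**
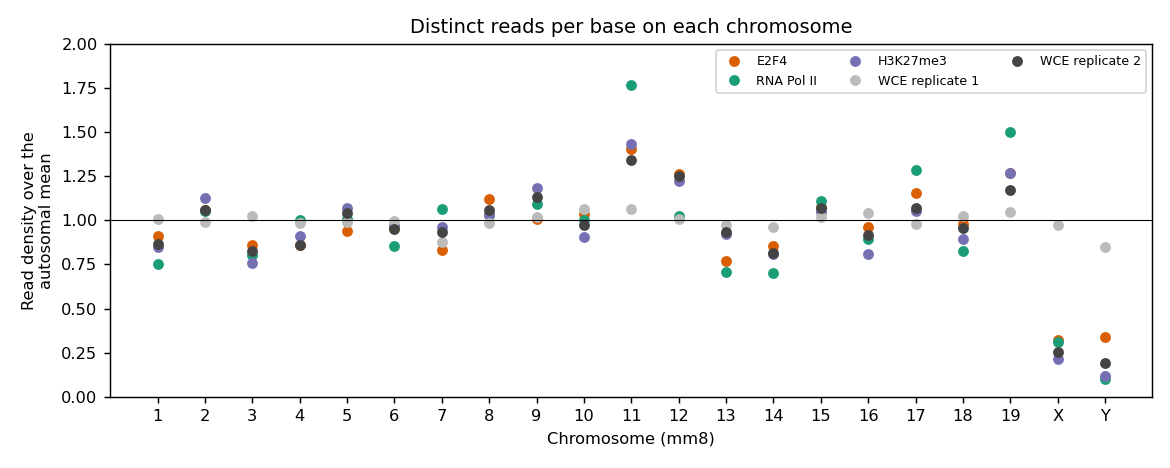
Distinct reads per base on each mm8 chromosome divided by the mean over the autosomes, 1 point per library. On X and Y, 4 libraries lie between 0.103 and 0.341, and WCE replicate 1 lies at 0.976 and 0.850.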

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

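The tests that gave 0.324, 0.850, 4.58 and 105 below, and the bound used for 0.121, were chosen only after related results had been seen. Reads listed at 2 places, which the comparisons above left out, also carried signal above WCE. They gave 283 E2F4 regions, 124 of them outside the regions described above, 2350 RNA Pol II regions (973 outside) and 453 H3K27me3 regions (299 outside). Such a read counts at both of its places, so the origin of each signal is not resolved.

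WCE replicate 1 had a read density on X of 0.976 of the autosomes, where the other 4 libraries had 0.216 to 0.324. Counting error at the lower depth is argued against, since WCE replicate 2 thinned to the same depth reached at most 0.258 in 100 draws. Random thinning keeps the expected ratio, so it cannot test other effects that come with a shallow library. The shorter read length is argued against, since E2F4 and RNA Pol II, with the same length, reached at most 0.324. Cells with 2 X chromosomes and no Y would not by themselves give its Y density of 0.850. Reads placed by chance would also fall on Y, so this density cannot decide which sex chromosomes the cells had. It also stays open that a large part of the reads of WCE replicate 1 may have been placed by chance rather than come from mouse chromatin. Over 1 Mb windows its counts correlated with those of WCE replicate 2 at r = 0.121. The 3 antibody libraries gave 0.774 to 0.893 with WCE replicate 2. The comparison set first, a thinned library that shows counting error only, gave at least 0.991. Reads placed independently by chance would not by themselves give the sharp peak at 43 bp between strands (37.0 times) described above. The source of that peak was not tested. No other biological explanation was tested. The WCE libraries are titled "WCE in 2nd MEF 1" and "WCE in 2nd MEF B2", and a difference between the cells or preparations behind these titles was not tested.

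WCE replicate 2 was denser in RNA Pol II regions than in their flanks, 3.47 times, and in E2F4 regions 4.53 times. Reads of the RNA Pol II library mixed into it are argued against as the only source, because in regions called from RNA Pol II without WCE its excess per RNA Pol II excess read was 4.58 times higher (3.95 to 5.08, 1000 resamples of regions) in the lowest of 10 classes of RNA Pol II density than in the highest, with classes set by reads not used in the measurement. A smaller admixture is not excluded. A property of the chromatin preparation stays open and may contribute, since the H3K27me3 library was also raised in RNA Pol II regions, 1.96 times over flanks. WCE replicate 1 went the other way, at 0.599 of its flanks (0.573 to 0.627). No biological explanation was tested.

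E2F4 regions lay in RNA Pol II regions in 87.5% of cases. E2F4 reads that are only a fixed share of the RNA Pol II reads are argued against, since E2F4 counts within 250 bp of 13394 RNA Pol II summits scattered around such a share with a Pearson dispersion of 105 (median squared residual 5.20), where counting error alone gives about 1. A looser unspecific part that follows RNA Pol II or open chromatin cannot be told apart from binding. The correlation across these summits, which are not independent replicates, was rho = 0.591, between the bounds of 0.3 and 0.6 set for it. Also predicted for such a part was a share of RNA Pol II regions with E2F4 that is highest in the densest class. This was met, at 63.8% against 4.70% in the lowest class. Binding of E2F4 at transcribed genes may account for the same values and was not tested, since no library with a nonspecific antibody was used here.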

How the results depend on the processing

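The uniform background, both sections and the minimum length for H3K27me3 were tests chosen after the data were seen. The excess of E2F4 regions in RNA Pol II regions kept its direction under all alternatives run, from 37.1 times the shifted regions (uniform background) to 149, while the share of E2F4 regions in them ranged from 50.6% to 94.2%. Leaving out a WCE library gave 1149 to 6255 E2F4, 6508 to 13319 RNA Pol II and 47 to 8658 H3K27me3 regions, the lower value each time against WCE replicate 1 alone, which has few reads. Other counts that moved were 22806 RNA Pol II and 16424 H3K27me3 regions with scaling on background bins, 5307 H3K27me3 regions at an adjusted p under 0.0001, 4577 at a fold minimum of 5 and 4775 after thinning, and 17773 E2F4 and 17321 H3K27me3 regions against a uniform background. The ratio of H3K27me3 regions in RNA Pol II regions to shifted ones ranged from 0.723 to 4.35 without 1 WCE library, the 4.35 resting on 2 of 47 regions. It lost its call at 0.754 (fold minimum 5) and 0.918 (bins of 1000 bp), and rose above its shifted range only at 4.26, against a uniform background. It passed 1 within the shifted range at 4.35, 1.01 (stricter p), 1.10 (thinning) and 2.73 (H3K27me3 against WCE replicate 1 and RNA Pol II against replicate 2). It was lower, at 0.183, with those WCE libraries exchanged, and at 0.593 for H3K27me3 regions of at least 10 kb; the 2.73 rests on 3 of 47 regions. For E2F4 the ratio ranged from 0.843 to 20 without 1 WCE library, turned to 1.42 after thinning and 4.37 against a uniform background, and passed 1 within the shifted range at 1.23 (fold minimum 5), 1.13 (bins of 1000 bp) and 2.27 (H3K27me3 against WCE replicate 1 and E2F4 against replicate 2, 1 of 47 regions). It fell outside the shifted range at 0.575 with scaling on background bins, 0.784 with both sections and 0.325 with H3K27me3 against WCE replicate 2 and E2F4 against replicate 1. The cause of these changes was not tested. For the named regions, 64 values stayed within their interval, 26 moved and none reversed. Of the 26, 10 are lower limits with 0 background reads left (4.34 to 20.3 against WCE replicate 1 alone, 119 for the first E2F4 region with no shift), so they do not show a lower ratio. With both sections the fourth E2F4 region had 54.0. The settings listed beforehand for promoters, promoter overlaps, gene lists, the promoter to gene body ratio and the transgenes were not run. No paired analysis was possible because each antibody has 1 library. At the E2F4 depth 12% of simulated bins raised 16-fold were called, so weaker sites at a usual WCE level are missed. The simulated bins were drawn at random, whereas WCE reads were 7.98 times denser in called E2F4 regions than in the genome. The share of sites missed at that WCE level was not simulated.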

Other observations

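The comparison of E2F4 regions inside and outside H3K27me3 regions was among the tests chosen after the data were seen. E2F4 regions inside H3K27me3 regions carried RNA Pol II less often than others. Of 135 such regions 59 overlapped an RNA Pol II region, 43.7% (35.2 to 52.5), against 5630 of 6367 outside, 88.4% (87.6 to 89.2). At the shares found outside within 10 classes of E2F4 density, 76.3% would have been reached. Besides the region on chromosome 5 from 114534501 to 114535000, an example among the 76 without an RNA Pol II region was chromosome 17 from 26142001 to 26142500, with an E2F4 ratio of 128 (41.9 to 637) an H3K27me3 ratio of 7.37 (2.15 to 39.0) and, from 6 reads that were too few for a call, an RNA Pol II ratio of 7.48 (1.60 to 46.3). Part of this difference may follow from how H3K27me3 regions were called, since their overlap with RNA Pol II turned from 0.741 to 4.26 times the shifted regions against a uniform background.

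The densest 1 Mb window for both E2F4 and RNA Pol II was chromosome 10 from 80000001 to 81000000, with 31 and 64 regions, against medians of 1 and 3 over 2579 windows. H3K27me3 regions were densest on chromosome 4 from 45000001 to 46000000 and on chromosome 14 from 62000001 to 63000000, with 35 each against a median of 1. Those windows held 12 and 5 RNA Pol II regions. Between the WCE libraries, 4776 regions were called in replicate 1 over replicate 2, and they overlapped 9 E2F4, 1 RNA Pol II and 25 H3K27me3 regions. In replicate 2 over replicate 1, 1 region was called, with 0 overlaps. No shifted regions were set against these overlaps.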
